A study of Homo sapiens with 12 samples.

How the data were processed

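The series follows primary human CD34+ cells, the stem and progenitor fraction selected from growth factor mobilized blood, through erythroid culture. Per the labels' protocols, purity by flow cytometry was above 95%, erythropoietin (EPO) was kept at 2 U/mL throughout, and interleukin-3 (IL-3) at 10 ng/mL was given until day 3. Stem cell factor (SCF) started at 50 ng/mL and was stepped down to 25 ng/mL at day 3, 10 ng/mL at day 6, 2 ng/mL at day 8 and 0 at day 10. The culture ran to day 16, and material was taken at days 0, 3, 7 and 10. The labels list 12 libraries: at each day 1 RNA-seq library, 1 pull-down of 5-hydroxymethylcytosine (5hmC, the oxidised form of methylated cytosine that TET enzymes make) and 1 input DNA library. Only values of the 4 RNA-seq libraries were used, and the other 8 libraries are not analysed here. The labels do not say whether the libraries came from 1 donor or 1 culture.

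RNA was extracted with Trizol and made into libraries with an Illumina protocol, per the labels. BWA and the hg19 genome build are named in the submitters' processing notes, with no version or role. The deposited table has 34440 rows, each with an Ensembl gene, 1 listed transcript of that gene, its common name, coordinates and transcript length. Per the file headers, each library has a count of mapped reads per gene and a value called transcripts per cell, both marked low stringency, a term the table does not define. The counts of mapped reads are the authors' whole-number values and were used as deposited. The other measurement, transcripts per cell, is a signal that the authors derived from the same reads: it equals reads divided by transcript length times 1 constant per library, with a largest relative deviation of 6.52e-09 over rows with more than 50 reads, and it is 0.594 times RPKM (reads per kilobase of transcript, scaled to the library total) in every library. It was not used further, because it holds no information beyond the counts. Transcript length, start and end are the deposited table's other columns, in bases, and coordinates are printed as given. A further 2 measurement columns match no sample in the labels and were not used.

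Several features of the table bear on the values. Each gene has 1 listed transcript, and for some genes it is short: the listed TET3 transcript has 470 bases, that of DNMT3A 677, that of PGK1 353 and that of JAK2 327, so the reads of such a gene may come from part of its messenger RNA only, and levels of different genes were not ranked against each other. The processed EEF1A1 pseudogene EEF1A1P5 holds 161540 reads at day 0 beside 340905 for EEF1A1 itself, so near-identical copies share reads. The pseudogene was looked up after the values were seen. Values of HBA1 and HBA2, HBG1 and HBG2, and other genes with near-identical copies, histones among them, are therefore uncertain as to which copy they belong to. Whether the counting used strand is not given in the sources used here, so overlapping genes cannot be separated. Of the rows, 1640 lie on alternative MHC or unplaced sequences. Where rows shared a symbol, the row with the highest mean over the 4 libraries stood for the gene, which left 33008 symbols and set aside 1432 rows.

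Counts were scaled to the library's total and are given as CPM. Total reads were 32699615 at day 0, 29816771 at day 3, 39792464 at day 7 and 36052970 at day 10. For the number of rows with a read, libraries were also thinned at random, without replacement, to the smallest total. With 1 library per day there is no replicate, no test and no p-value. A fixed rule of size was used instead, chosen before the data were examined: a gene counted as higher or lower when log2(CPM + 1) differed by at least 1 (2-fold) and the larger of both CPM values was at least 1. Genes whose larger value reached 1 CPM are called detected. This scale understates the change of genes with few reads. Each named fold is the plain ratio of CPM values with an exact conditional (Poisson) 95% interval. Against a count of 0 the fold is a lower bound computed with 3 counts in the library at 0. Intervals and bounds cover only the counting error of independent reads. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. They say nothing of the variation between cultures.

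Gene lists were described by the median log2 ratio of their detected members, its 95% order-statistic interval, the number of members past the size rule, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. There were 25 lists fixed before the data were examined: globin genes; haem synthesis; iron handling; red cell membrane, skeleton and blood group proteins; erythroid transcription factors; red cell enzymes and antioxidants; autophagy and organelle clearance. The signalling, progenitor and cell type lists were EPO, SCF and IL-3 signalling; stem and early progenitor; HOXA and HOXB clusters; granulocyte and monocyte; lymphoid; megakaryocyte; mast cell, basophil and eosinophil; HLA class II presentation. The general lists were DNA methylation and hydroxymethylation enzymes and readers, proliferation and mitosis, DNA replication, cholesterol synthesis, glycolysis, immediate-early and handling stress, interferon response, cytosolic ribosomal proteins, replication-dependent histones and a housekeeping reference. Transcripts of the histone list mostly lack a poly(A) tail, so their counts may depend on how RNA was selected for the libraries. All 477 member entries were found in the table. A further 8 lists, used only in the closing section and in the figure of list levels, were written after the leading genes had been seen.

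Genes are named by a rule fixed before the data were examined: for each of 4 comparisons, the 10 largest differences in each direction; from each list, up to 4 detected members with the largest difference in the comparison spoken of, and any member for its level at the 4 days; and always the TET and DNMT enzymes, GATA1, GATA2, KLF1, TAL1, SPI1, CD34, KIT, HBB, HBG1 and HBG2. Genes whose level could bear on a person's identity were left out of the text, and not every gene that meets the rule is named. The alternatives were pseudocounts of 0.1 and 5 CPM, no floor or a floor of 5 CPM, median-of-ratios scaling, upper-quartile scaling, scaling without the globin genes, the sum of rows that share a symbol, and a 4-fold threshold. The size rule was tested on simulated counts drawn at the real libraries' means and depths. The changed genes were drawn only from rows with a mean of at least 5 CPM, so changes in genes near the floor of 1 CPM were not tried. Of 50 genes changed 3-fold, 50 were called for day 3 against day 0, and 0 of 50 changed 1.5-fold. For day 10 against day 0, 49 of 50 genes changed 3-fold were called. At such levels the rule nearly fixes these outcomes. None of 17032 unchanged genes was called in the simulated comparison of day 3 against day 0, which holds counting noise but no variation between cultures. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.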

Results

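Gene expression was followed in human CD34+ blood progenitors during culture toward red cells, with 1 RNA-seq library at each of days 0, 3, 7 and 10. Day 0 is the purified starting population, day 3 ends the phase with IL-3, and days 7 and 10 fall in the phase with EPO and declining SCF. The series pairs these libraries with maps of 5hmC, and the RNA measurements show how the enzymes that write and oxidise DNA methylation, and the genes of each blood lineage, differed between days. Reads assigned to genes numbered 32699615, 29816771, 39792464 and 36052970 at days 0, 3, 7 and 10. Reads were found on 26724 of the 34440 rows at day 0, 24831 at day 3, 24765 at day 7 and 24093 at day 10, or 26565, 24831, 24341 and 23774 after thinning each library to 29816771 reads. All differences below are between single libraries and have no replicate check. Member counts with median-of-ratios scaling are given for some lists only, so a list without them need not be unchanged by that scaling. Ranges after a fold are 95% counting intervals, and ranges after a list median, given as a log2 ratio, are order-statistic intervals over its members.

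Across the 4 days, 13166 genes differed at least 2-fold between their highest and lowest day. Of these, 6708 were highest at day 0, 2800 at day 3, 1483 at day 7 and 2175 at day 10. Levels were higher at every step in 925 genes and lower at every step in 3442. With median-of-ratios scaling the day of highest expression, highest at day 10, had 3347 genes, and 1437 genes were in the class day of highest expression, higher at every step. The globin genes, which encode the chains of haemoglobin, took 0.00254% of reads at day 0 (0.00238% to 0.00272%, Wilson 95% interval), 0.299% at day 3, 1.41% at day 7 and 6.03% at day 10. How reads matching several near-identical copies were counted is not known here. These shares and the library totals may therefore hold some reads more than once.

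**Figure D1:**
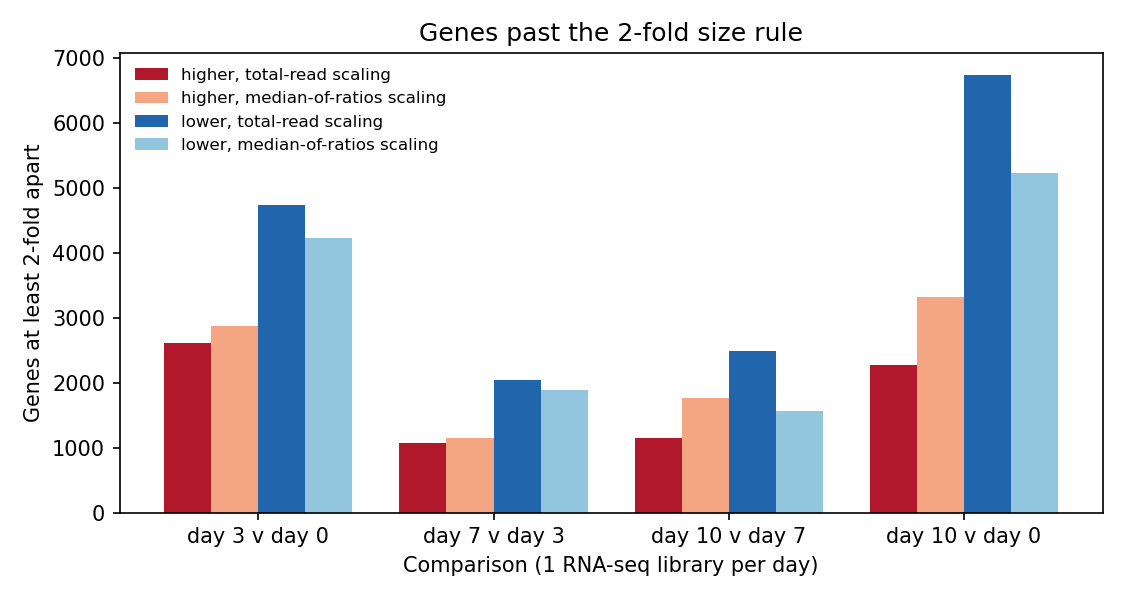
Number of genes at least 2-fold higher (red) or lower (blue) in the later library of each of 4 comparisons, with total-read scaling (dark bars) and median-of-ratios scaling (light bars); each day has 1 library. With total-read scaling lower genes outnumber higher genes in all 4 comparisons, while with median-of-ratios scaling the counts for day 10 against day 7 are 1765 higher and 1572 lower.

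The enzymes of cytosine methylation and its oxidation differed widely in course. TET2 (ENSG00000168769, chromosome 4, 106067032 to 106163928), a dioxygenase that converts methylated cytosine to 5hmC, was at 73, 5.8, 6.46 and 12.7 CPM at days 0, 3, 7 and 10, so that day 3 was 12.6-fold lower (10.8 to 14.8) than day 0 and day 10 was 1.97-fold higher (1.69 to 2.31) than day 7. TET1 (ENSG00000138336, chromosome 10, 70320413 to 70454239) was at 19.4, 5.74, 6.51 and 3.11 CPM at days 0, 3, 7 and 10 and 3.39-fold lower (2.86 to 4.03) at day 3 than at day 0. TET3 (ENSG00000187605, chromosome 2, 74213653 to 74220867), counted on a transcript of 470 bases, had 30, 6, 12 and 87 reads at days 0, 3, 7 and 10, which made day 10 8.0-fold higher (4.36 to 16.1) than day 7. DNMT1 (ENSG00000130816, chromosome 19, 10244023 to 10305755), which copies methylation onto newly made strands, was at 145, 329.8, 425 and 501 CPM at days 0, 3, 7 and 10. The methyltransferases that set new marks were lower at days 7 and 10 than at day 0: DNMT3B (ENSG00000088305, chromosome 20, 31350191 to 31397162) was at 81.7, 89.6, 30.5 and 7.35 CPM at days 0, 3, 7 and 10, and DNMT3A (ENSG00000119772, chromosome 2, 25455496 to 25469175), counted on a transcript of 677 bases, at 15.9, 2.31, 0.679 and 0.222 CPM at days 0, 3, 7 and 10. DNMT3L, their catalytically inactive partner, had 13 reads at day 0 and 0 at the later days, under 1 CPM throughout. The reads of TET3 and DNMT3A may come from part of their messenger RNA only, so their courses need not be those of the whole gene.

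In the wider list of methylation and hydroxymethylation enzymes and readers, 7 of 19 detected members were higher, 5 lower and 7 neither at day 3 against day 0. Among the higher was UHRF1 (5.23-fold, 4.95 to 5.53), which brings DNMT1 to replicated DNA, and MBD3 (3.81-fold, 3.59 to 4.04), a subunit of a chromatin remodelling complex. At day 7 against day 3, 0 of 18 were higher and 1 lower, and at day 10 against day 7, 1 higher and 1 lower, or 3 and 1 with median-of-ratios scaling. At day 10 against day 0 the list median was 0.25 (-0.82 to 0.81), with 4 of 20 members higher and 5 lower, and 9 higher and 5 lower with median-of-ratios scaling. The median at day 10 against day 7 was -0.02, and 0.26 with that scaling.

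**Figure D2:**
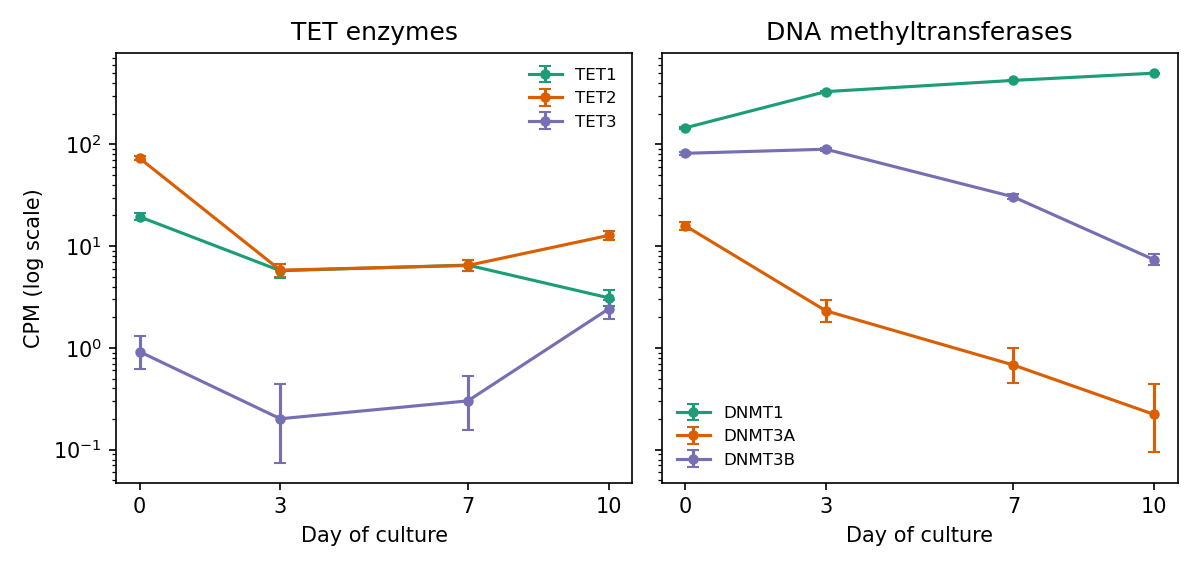
CPM on a log axis by day of culture for TET1, TET2 and TET3 (left) and DNMT1, DNMT3A and DNMT3B (right), 1 library per day, with exact Poisson 95% intervals of the counts as bars. TET2 goes from 73 CPM at day 0 to 5.8 at day 3, DNMT1 reaches 501 CPM at day 10 and DNMT3A is at 0.222. DNMT3L, with reads only at day 0, is not drawn. TET3 and DNMT3A are counted on listed transcripts of 470 and 677 bases, which may cover part of the messenger RNA only.

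The first comparison, day 3 against day 0, asks what differs once progenitors have been cultured with EPO, SCF and IL-3. Fetal and adult globin transcripts were far higher at day 3: HBG1 (ENSG00000213934, chromosome 11, 5269313 to 5271122) and HBG2, the gamma chains of fetal haemoglobin, were 2019-fold higher (979 to 5022) and 3877-fold higher (1073 to 32023), from 7 and 2 reads at day 0, and HBB (ENSG00000244734, chromosome 11, 5246694 to 5248427) was 131-fold higher (117 to 148). Transcripts of eosinophil proteins were also among the largest differences. The peroxidase EPX was 175-fold higher (141 to 220.3), the Charcot-Leyden crystal protein CLC 120.1-fold higher (107 to 135) and the major basic protein PRG2 102-fold higher (92.8 to 112). PSAT1, an enzyme of serine synthesis, was 226-fold higher (144 to 376), and NCS1, a neuronal calcium sensor, 419-fold higher (192 to 1143) from 6 reads. JUN (ENSG00000177606, chromosome 1, 59246465 to 59249785), a subunit of the AP-1 transcription factor, was 409-fold lower (353 to 478), at 2389 CPM at day 0 and 5.84 at day 3.

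Of 17754 detected genes, 2619 were higher at day 3 and 4738 lower, and the median log2 ratio of all detected genes was -0.31. The transcription factor KLF2 was 185-fold lower (137 to 256), the small GTPase RHOB 189-fold lower (131 to 285) and the AP-1 subunit FOSB 163-fold lower (111 to 250.5). The histone gene HIST2H2BE was 72.5-fold lower (62.3 to 84.8) and HIST2H2AA4, which has a near-identical copy, 81.2-fold lower (65.5 to 102). The long non-coding RNA MIAT was 65.2-fold lower (53.9 to 79.6) and DPYSL3, a cytoskeletal regulator, 67.1-fold lower (53.4 to 85.6). MAMDC2 and WDR49 completed the leading lower genes at 185-fold lower (114 to 325) and 263-fold lower (128 to 656).

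Erythroid genes were partly higher at day 3. All 8 detected globin genes were higher, with a median log2 ratio of 6.08 (3.07 to 8.48). GATA1 (ENSG00000102145, chromosome X, 48644962 to 48652715), the zinc-finger factor required for red cell formation, was 10.9-fold higher (10.1 to 11.9), and KLF1 (ENSG00000105610, chromosome 19, 12995236 to 12998017), an activator of beta-globin, 14.2-fold higher (12.8 to 15.7). Their list had 5 of 15 members higher, 1 lower and 9 neither. Among red cell membrane and skeleton genes 12 of 24 were higher and 4 lower, led by RHAG (44-fold, 30.5 to 66), an ammonium channel of the Rh complex, and the spectrin gene SPTB (16.2-fold, 11.3 to 24.1). Haem synthesis had 5 of 11 higher and 0 lower, including ALAS2 (19.5-fold, 12.1 to 33.3), the erythroid rate-limiting enzyme, and UROS (4.4-fold, 3.84 to 5.05). Red cell enzymes had 9 of 15 higher and 1 lower. In that list the alpha-globin chaperone AHSP was 108-fold higher (52.2 to 269.9), while the nuclear protein HEMGN was 19.1-fold lower (16.7 to 21.8). Iron handling had 4 of 13 higher and 1 lower, with GLRX5 (5.35-fold, 4.98 to 5.74), an iron-sulphur cluster protein, the largest.

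Cell division genes were mostly higher at day 3. All 20 genes of proliferation and mitosis were higher at day 3, with a median of 4.16 (3.21 to 4.52), above all 10000 matched random lists at percentile 100. Examples were the mitotic kinase PLK1 (74.1-fold, 59.7 to 93.2), the anaphase activator CDC20 (57.7-fold, 47.4 to 71.1) and the spindle-associated BIRC5 (42.7-fold, 36.5 to 50.4). DNA replication followed with 22 of 24 higher and a median of 2.27 (2.01 to 2.93), led by RRM2 (21.7-fold, 19.8 to 23.9), a subunit of ribonucleotide reductase. Glycolysis had 7 of 18 higher and 0 lower, or 11 higher with median-of-ratios scaling, with PGAM1 (6.55-fold, 6.16 to 6.97) and TPI1 (4.16-fold, 4.06 to 4.27) among them. The housekeeping reference was itself not level, with 8 of 18 higher, 1 lower and a median of 0.83 (0.51 to 1.47), including ACTB (4.19-fold, 4.15 to 4.23). Ribosomal proteins had 0 of 45 members past 2-fold and a median of -0.21 (-0.41 to -0.09). Cholesterol synthesis had 4 of 18 higher and 2 lower, or 6 and 2 with median-of-ratios scaling.

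Genes of stem and early progenitor cells were lower in 19 of 24 cases and higher in 0, with a median of -2.66 (-3.09 to -1.51) at percentile 0. The transcription factor HLF was 27.7-fold lower (23.1 to 33.6), the corticotropin-releasing hormone binding protein CRHBP 25.8-fold lower (23.4 to 28.6), and CD34 (ENSG00000174059, chromosome 1, 208057594 to 208072479), the surface marker used for selection, 8.21-fold lower (7.59 to 8.9). HOXA and HOXB genes, which pattern the body axis and are active in blood progenitors, were lower in 10 of 14 and higher in 0, as in HOXA6 (38.3-fold, 22.6 to 70.5) and HOXA3 (11.2-fold, 9.14 to 13.9). HLA class II presentation was lower in 10 of 11, including its transactivator CIITA (6.64-fold, 6.29 to 7.01). Immediate-early genes, which respond within minutes to stimulation and cell handling, were lower in 17 of 19 and higher in 1, with the phosphatase DUSP1 (49.4-fold, 44.4 to 55) and the antiproliferative BTG2 (46.8-fold, 39.2 to 56.4) among them. Interferon response genes were lower in 11 of 18 and higher in 1, as in OAS2 (13-fold, 10.6 to 15.9), and replication-dependent histones lower in 9 of 17 and higher in 2. Transcripts of the histone list mostly lack a poly(A) tail, so these counts need not follow histone expression.

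Markers of other blood lineages differed in direction. Mast cell, basophil and eosinophil genes were higher at day 3 in 10 of 13 and lower in 0, with a median of 1.94 (0.19 to 6.57). Granulocyte and monocyte genes split into 9 higher and 5 lower of 20, and the higher ones included the neutrophil granule proteases PRTN3 (81.2-fold, 72.1 to 92), CTSG (45.4-fold, 36.8 to 56.6) and ELANE (31.2-fold, 27.6 to 35.3). SPI1 (ENSG00000066336, chromosome 11, 47376411 to 47400127), a transcription factor of myeloid cells, was 1.3-fold higher (1.24 to 1.36). Lymphoid genes were lower in 10 of 16 and higher in 3, with DNTT (34.2-fold, 26.9 to 44.2), the terminal transferase of lymphoid precursors, the largest. Megakaryocyte genes had 5 of 13 higher, such as the platelet integrin ITGA2B (6.44-fold, 6.08 to 6.84), and 3 lower. In EPO, SCF and IL-3 signalling 4 of 16 were higher and 6 lower, with EPOR (4.09-fold, 3.58 to 4.69), the EPO receptor, higher and SOCS3 (4.98-fold, 3.98 to 6.28), a feedback inhibitor, lower. Its median of -0.12 became 0.15 with median-of-ratios scaling and 0.10 with upper-quartile scaling. Autophagy genes had 0 of 13 higher and 3 lower, or 2 and 3 with median-of-ratios scaling.

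The next step, day 7 against day 3, covers the phase after IL-3 was left out. SLC4A1 (ENSG00000004939, chromosome 17, 42325753 to 42345509), the band 3 anion exchanger of the red cell membrane, was 580.1-fold higher (432 to 798) at day 7, at 1.48 and 856 CPM. ALAS2 was 53.4-fold higher (47.8 to 59.8) and HEMGN, which had been lower at day 3 than at day 0, 50.5-fold higher (44.4 to 57.6). SOX6, a transcription factor of late erythroid cells, was 132-fold higher (60.4 to 360.2) from 6 reads. CD34 was 61-fold lower (36.7 to 109.7), with 15 reads left at day 7.

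Of 16082 detected genes, 1072 were higher and 2040 lower, with a median log2 ratio of -0.06. Other leading higher genes were LRP1, a large endocytic receptor, 51.6-fold higher (42.1 to 64), AHSP 25.9-fold higher (24 to 28), glycophorin B, GYPB, 51.1-fold higher (35 to 77.7), and the membrane skeleton genes EPB42 and ADD2, 27.6-fold higher (24.2 to 31.7) and 25.2-fold higher (22.9 to 27.7). Leading lower genes included the protease inhibitor SPINK2 at 34.9-fold lower (22.4 to 57.6), the transcription factor MYCN at 30.8-fold lower (19.9 to 50.1) and NPDC1 at 26.6-fold lower (20.0 to 35.9). PTPRCAP, which binds the leukocyte phosphatase CD45, was 21.4-fold lower (17.3 to 26.9), and TNFRSF8, the CD30 receptor, 23-fold lower (16.8 to 32.3). FUT7, a fucosyltransferase, was 20.1-fold lower (15.2 to 27.2), CPXM1 18.3-fold lower (16 to 21), the receptor-like pseudokinase PTK7 15.8-fold lower (12.8 to 19.7) and the small GTPase RAB34 15.3-fold lower (13.1 to 18).

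Red cell membrane and skeleton genes were higher in 22 of 26 and lower in 0, with a median of 2.30 (1.64 to 3.23) at percentile 100. Haem synthesis had 6 of 11 higher and 0 lower, with ALAD (4.62-fold, 4.41 to 4.85) and FECH (3.97-fold, 3.82 to 4.13), which inserts iron into the porphyrin ring. Globin genes had 6 of 9 higher, such as HBA2 (8.15-fold, 7.99 to 8.31), and 1 lower. The mitochondrial iron importer SLC25A37 was 8.38-fold higher (8.07 to 8.69) and the transferrin receptor TFRC 5.14-fold higher (4.75 to 5.57), in a list with 5 of 13 higher and 0 lower. Red cell enzymes had 10 of 15 higher and 1 lower, with carbonic anhydrase CA1 (15.1-fold, 14.2 to 16) and erythroid pyruvate kinase PKLR (11.7-fold, 10.9 to 12.7). Erythroid transcription factors had 6 of 16 higher and 1 lower, and KLF1 was 3.3-fold higher (3.2 to 3.4).

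Stem and early progenitor and HLA class II genes were mostly lower at day 7. The stem and early progenitor list had 18 of 21 lower and 0 higher, or 1 higher with median-of-ratios scaling, with a median of -2.68 (-3.17 to -1.14). GATA2 (ENSG00000179348, chromosome 3, 128198270 to 128212028), the GATA factor of progenitors, was 2.62-fold lower (2.53 to 2.71). All 11 HLA class II presentation genes were lower, including HLA-DRA (8.25-fold, 7.33 to 9.3) and the invariant chain CD74 (7.11-fold, 6.86 to 7.38). HOXA and HOXB genes were lower in 6 of 12, and lymphoid genes in 8 of 9, with 0 higher in either. Granulocyte and monocyte genes were lower in 11 of 20 and higher in 1, among them PRTN3 (9.42-fold, 9.06 to 9.8), CEBPA (9.88-fold, 9.0 to 10.9), a transcription factor of granulocyte formation, and CD33 (10.3-fold, 8.65 to 12.2). SPI1 was 5.63-fold lower (5.25 to 6.05). Mast cell, basophil and eosinophil genes were lower in 4 of 12 and higher in 0, and megakaryocyte genes lower in 5 of 13 and higher in 2, or 2 and 2 with upper-quartile scaling.

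Glycolysis genes were lower in 8 of 18 and higher in 2, with a median of -0.93 (-1.41 to -0.06). The listed pyruvate kinase PKM2 was 10.0-fold lower (9.71 to 10.4) and enolase ENO1 3.64-fold lower (3.59 to 3.7). Genes of proliferation and mitosis had 0 of 20 past 2-fold and DNA replication 1 of 24 higher and 0 lower. Immediate-early genes had 7 of 17 higher, led by FOS (11.1-fold, 9.83 to 12.6), and 2 lower. Interferon response had 2 of 15 higher and 4 lower, ribosomal proteins 1 of 45 higher and 4 lower, and the housekeeping reference 0 of 18 higher and 2 lower. In the EPO, SCF and IL-3 signalling list 1 of 15 was higher, EPOR at 3.06-fold higher (2.86 to 3.27), and 1 lower, the kinase LYN at 2.23-fold lower (2.0 to 2.48).

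Day 10 against day 7 compares the last step covered, during which SCF was tapered to its end. BCAM, the laminin-binding Lutheran glycoprotein, was 61.2-fold higher (46.5 to 82.1) at day 10, and SLC4A1 again among the leading genes at 16.3-fold higher (16.1 to 16.5), reaching 13949 CPM. The pseudokinase TRIB3 was 35.2-fold higher (28.9 to 43.2), the glutathione-degrading enzyme CHAC1 20.0-fold higher (17.6 to 22.8) and DDIT4, an inhibitor of mTOR signalling, 16.7-fold higher (16.3 to 17.2). Lactate dehydrogenase LDHA (ENSG00000134333, chromosome 11, 18415935 to 18429765) was 9.02-fold lower (8.6 to 9.45) and the cytokine MIF 13.5-fold lower (12.1 to 15). KIT (ENSG00000157404, chromosome 4, 55524085 to 55606881), the receptor of SCF, was 3.11-fold lower (2.95 to 3.27).

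Of 15426 detected genes, 1154 were higher and 2496 lower, so that 31.6% of the genes past the rule were higher. With median-of-ratios scaling 1765 were higher and 1572 lower, 52.9% higher, and the median log2 ratio of all detected genes was -0.02 in place of -0.28. Genes and lists with a log2 ratio close to 0 can therefore differ in direction between the scalings. Other leading higher genes were the growth factor IGF2 at 56.2-fold higher (42 to 76.9), the glycine transporter SLC6A9 at 23.7-fold higher (21.4 to 26.2) and the fatty acyl-CoA synthetase ACSL6 at 70.7-fold higher (41.1 to 133). LRRN2 was 23.2-fold higher (19.3 to 28.2) and the focal adhesion protein TNS1 16.1-fold higher (15.5 to 16.7). Leading lower genes were LY6E, a GPI-anchored surface protein, at 23.1-fold lower (17 to 32.3), the intermediate filament gene DES at 17.4-fold lower (13.8 to 22.3), the caveolar protein PTRF at 13.6-fold lower (11.4 to 16.5) and IGLL1, a surrogate light chain, at 20.3-fold lower (14.5 to 29.1). IL2RG, the common cytokine receptor gamma chain, was 15.1-fold lower (12 to 19.3), the neuropeptide GAL 32.9-fold lower (19.7 to 59.1) and the secreted EGFL7 12-fold lower (10.1 to 14.3). AP000350.4, at 10.3-fold lower (9.0 to 11.7), overlaps MIF in position.

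Membrane and skeleton genes were higher in 24 of 26 and lower in 0, with a median of 2.37 (1.69 to 3.24), including TMCC2 (16.8-fold, 14.2 to 20.1) and TSPO2 (14.3-fold, 12.2 to 17). Haem synthesis had 7 of 11 higher, with ALAS2 (5.57-fold, 5.49 to 5.65), and 0 lower. Globin genes had 5 of 10 higher and 1 lower. HBB was 4.11-fold higher (4.09 to 4.13) and HBA1 5.12-fold higher (5.09 to 5.15), while HBG1 was at 1097 and 1217 CPM and HBG2 at 510.4 and 509. Erythroid transcription factors had 7 of 16 higher, as in SOX6 (12-fold, 11.2 to 12.8) and FOXO3 (4.5-fold, 4.36 to 4.65), and 2 lower, as in MYB (3.2-fold, 3.09 to 3.31), a factor of immature cells. TAL1 (ENSG00000162367, chromosome 1, 47681963 to 47697387), a partner of GATA1, was 2.67-fold higher (2.61 to 2.73). SLC25A37 was 6.23-fold higher (6.16 to 6.3), in an iron list with 3 of 13 higher and 1 lower, or 4 and 0 with median-of-ratios scaling. Autophagy and organelle clearance genes had 4 of 14 higher, such as ATG4A (4.75-fold, 4.41 to 5.12) and GABARAPL1 (4.54-fold, 4.06 to 5.09), and 2 lower. With median-of-ratios scaling 7 were higher. Red cell enzymes had 6 of 15 higher and 2 lower, or 10 higher with that scaling.

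Glycolysis was lower in 13 of 18 and higher in 1, or 12 and 2 with median-of-ratios scaling, with a median of -1.99 (-2.51 to -0.67). GPI, the second enzyme of the pathway, was 8.48-fold lower (7.98 to 9.02) and ENO1 7.89-fold lower (7.59 to 8.2), while the glucose transporter SLC2A1 was 6.52-fold higher (6.35 to 6.7). Ribosomal proteins had a median of -0.82 (-0.91 to -0.75), or -0.53 with median-of-ratios scaling, with 0 of 45 higher and 5 lower, or 2 lower with that scaling. Proliferation and mitosis had 7 of 20 higher, such as MKI67 (3.08-fold, 3.04 to 3.12), and 0 lower, or 11 higher with that scaling. Immediate-early genes had 8 of 19 higher, such as ATF3 (14.9-fold, 10.5 to 21.9) and JUNB (4.15-fold, 4.04 to 4.27), and 1 lower. With median-of-ratios scaling 11 were higher. In the EPO, SCF and IL-3 signalling list 4 of 15 were higher, among them BCL2L1 (4.51-fold, 4.37 to 4.65), which protects late erythroid cells from death, and 5 lower, among them STAT5A (6.17-fold, 5.86 to 6.49), or 5 higher and 3 lower with median-of-ratios scaling.

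Mast cell, basophil and eosinophil genes were lower in 7 of 12 at day 10 and higher in 0, with PRG2 (8.65-fold, 8.35 to 8.97) and EPX (6.76-fold, 6.55 to 6.98). Granulocyte and monocyte genes were lower in 9 of 21 and higher in 1, with 6 lower under median-of-ratios scaling, and megakaryocyte genes lower in 8 of 11 and higher in 1. HLA class II genes were lower in 7 of 8 and higher in 0, or lower in 5 with median-of-ratios scaling. Of the stem and early progenitor list 11 members were still detected, of which 2 were lower and 0 higher, or 1 higher with median-of-ratios scaling. HOXA and HOXB genes had 3 of 9 higher and 1 lower at day 10, or 3 and 0 with median-of-ratios scaling, and a median of -0.76 (-0.84 to 1.39). Interferon response had 1 of 13 higher and 3 lower, or 1 and 1 with that scaling, and DNA replication 3 of 24 higher and 0 lower. Replication-dependent histones had 0 of 17 past 2-fold. The housekeeping reference had 0 of 18 higher and 5 lower, or 2 lower with median-of-ratios scaling, and cholesterol synthesis 2 of 18 higher and 1 lower.

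**Figure D3:**
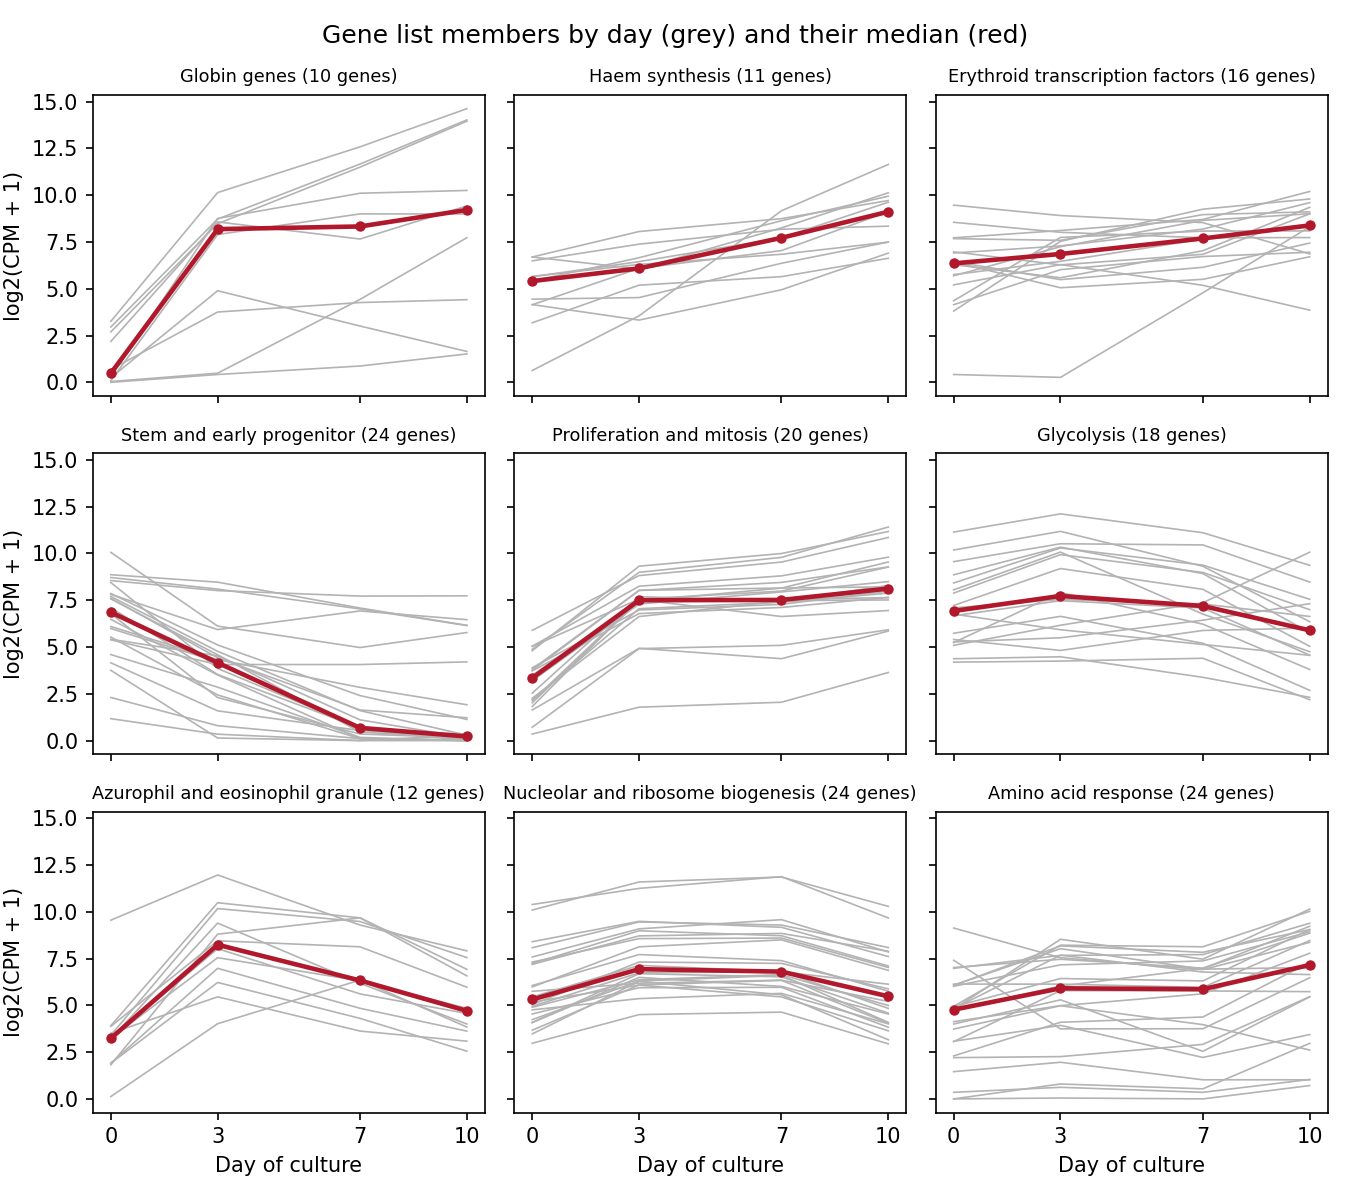
Levels of the members of 9 gene lists as log2(CPM + 1) by day of culture, 1 library per day, each grey line 1 gene and the red line the median of all members. The median of the globin genes goes from 0.48 at day 0 to 9.21 at day 10 and that of stem and early progenitor genes from 6.86 to 0.22; the lists of granule, nucleolar and amino acid response genes were written after the data were seen.

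Over the whole interval, day 10 against day 0, red cell genes were the leading higher genes. SLC4A1 was 16290.3-fold higher (11271 to 24516), HBB 2939.6-fold higher (2615 to 3317), HBA2 2898-fold higher (2503 to 3374) and ALAS2 5800.4-fold higher (3670 to 9787). AHSP was 5529.9-fold higher (2684 to 13755), SPTB 1546-fold higher (1089 to 2276) and RHAG 1368-fold higher (952 to 2043). Among the leading lower genes the LIM-domain protein FHL1, with 4 reads at day 10, was 4173-fold lower (1629.5 to 15318), CRHBP, with 2 reads, 6259-fold lower (1732 to 51686), and CD34, with 3 reads, 2271-fold lower (777 to 11013). DPYSL3 had no read at day 10 and was at least 2001-fold lower.

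Of 17786 detected genes, 2276 were higher and 6747 lower, so that 25.2% of the genes past the rule were higher. With median-of-ratios scaling the counts were 3317 and 5238, 38.8% higher, and the median log2 ratio of all detected genes was -0.23 in place of -0.61. Other leading lower genes were ANGPT1, a ligand of the TIE2 receptor, at 933-fold lower (473 to 2161), C5orf23 at 913-fold lower (544 to 1671), the interferon-induced GTPase GBP2 at 397-fold lower (269 to 614) and the non-coding KIAA0125 at 535-fold lower (324 to 956). The early activation antigen CD69 was 176-fold lower (148 to 213). GATA1 was 13.9-fold higher (12.9 to 15.1), KLF1 68.3-fold higher (62 to 75.3) and TAL1 6.49-fold higher (6.28 to 6.71), while GATA2 was 6.59-fold lower (6.32 to 6.87), SPI1 12.9-fold lower (11.4 to 14.6) and KIT 3.18-fold lower (3.02 to 3.36).

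All 10 globin genes and all 11 haem synthesis genes were higher at day 10 than at day 0, with medians of 8.30 (1.52 to 11.26) and 3.43 (1.86 to 4.97). Membrane and skeleton genes were higher in 25 of 26, with a median of 5.70 (3.87 to 7.24), and 0 were lower. Red cell enzymes were higher in 11 of 15 and lower in 1, and erythroid transcription factors higher in 11 of 16 and lower in 2, or 12 and 1 with median-of-ratios scaling. Iron handling genes were higher in 6 of 13 and lower in 0, including SLC25A37 (97.2-fold, 92.8 to 102) and TFRC (28.8-fold, 26.6 to 31.3). Proliferation and mitosis was higher in 20 of 20 with a median of 5.09 (4.39 to 5.70), and DNA replication in 23 of 24 with a median of 2.52 (1.94 to 3.06). Autophagy and organelle clearance genes were higher in 5 of 13 and lower in 0.

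Stem and early progenitor genes were lower in 23 of 24 and higher in 0, with a median of -4.93 (-6.63 to -2.70), or -5.53 with genes at 0 reads placed at their bound. All 11 HLA class II genes were lower, with a median of -5.05 (-6.13 to -4.01), as were all 14 detected lymphoid genes, with a median of -2.57 (-4.47 to -1.23), or -4.12 at the bound. With median-of-ratios scaling 21 stem and early progenitor genes, 11 HLA class II genes and 12 lymphoid genes were lower. HOXA and HOXB genes were lower in 10 of 15 and higher in 2, and megakaryocyte genes lower in 7 of 10 and higher in 1. Ribosomal proteins were lower in 28 of 45 and higher in 1, or lower in 18 with median-of-ratios scaling, with RPS29 (11.5-fold, 11 to 12) the largest. Glycolysis was lower in 12 of 18 and higher in 2, with a median of -1.89 (-2.20 to -0.87), while SLC2A1 was 32.4-fold higher (30.5 to 34.4). Immediate-early genes were lower in 13 of 20 and higher in 1, or 12 and 2 with median-of-ratios scaling. Interferon response genes were lower in 12 of 18 and higher in 2, and replication-dependent histones lower in 9 of 18 and higher in 2.

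The remaining lists were mixed at day 10 against day 0. Granulocyte and monocyte genes were higher in 4 and lower in 10 of 21, or 7 and 9 with median-of-ratios scaling. Mast cell, basophil and eosinophil genes were higher in 4 and lower in 1 of 13, with EPX still 47.4-fold higher (38.2 to 59.7), and their median of -0.21 became 0.21 with that scaling. The EPO, SCF and IL-3 signalling list was higher in 5 and lower in 7 of 16, with EPOR 27.8-fold higher (24.7 to 31.5) and LYN 34.3-fold lower (28.3 to 41.9). Cholesterol synthesis was higher in 2 and lower in 1 of 18, with a median of -0.06, or 5 and 1 with a median of 0.37 with that scaling. The housekeeping reference was higher in 2 and lower in 3 of 18, or 7 and 3.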

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

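All alternatives in this part were fixed before the data were examined. No paired analysis was possible because each day has 1 library. Among the 100 list medians and 141 named differences, none of those past the size rule changed direction under the alternatives, while some list medians near 0 did. For the named differences this outcome was nearly fixed in advance. Pseudocounts and floors cannot turn the direction of a gene. Each scaling shifts a comparison by much less than 2-fold, with median-of-ratios factors of 1.13 at day 0 and 0.83 at day 10. A floor of 5 CPM, no floor, a pseudocount of 0.1, upper-quartile scaling, scaling without globin genes and summed rows each left all 8 gene counts and all 6 counts by day within 1.5 times their values. Median-of-ratios scaling gave 1765 higher and 1572 lower genes for day 10 against day 7, which reverses the balance of 1154 and 2496. For the day of highest expression, highest at day 10 had 3347 genes and, again for the day of highest expression, higher at every step had 1437. All 1154 genes higher at day 10 than at day 7 with total-read scaling were among the 1765. That overlap follows from the scaling, which moves all ratios of day 10 over day 7 upward, and lends the calls no support. A pseudocount of 5 CPM, which shrinks the ratios of genes with few reads, gave 2674 lower genes for day 3 against day 0, 565 higher and 1030 lower for day 7 against day 3, 753 higher and 1343 lower for day 10 against day 7, and 4118 lower for day 10 against day 0. For the day of highest expression, highest at day 0 then had 4164 genes. The stricter 4-fold threshold left 625 higher and 1352 lower genes for day 3 against day 0 and 168 and 387 for day 7 against day 3. Of the genes at least 2-fold higher, day 10 against day 7 kept 204 at 4-fold, and of the genes at least 2-fold lower, day 10 against day 7 kept 295. Of the genes at least 2-fold higher, day 10 against day 0 kept 932, and of the genes at least 2-fold lower, day 10 against day 0 kept 2854. With that threshold 3019, 1059, 390 and 1009 genes were highest at days 0, 3, 7 and 10. It left 556 genes higher at every step, and, for the day of highest expression, lower at every step had 1981. Of the 100 list medians, 96 stayed within their order-statistic interval with median-of-ratios scaling, 95 with a pseudocount of 5 and 89 with a pseudocount of 0.1, and for those that left it the cause was not tested. Of the 141 named differences, 93 moved by no more than the mean reach of their counting interval to either side on the log2 scale with median-of-ratios scaling, and 45 with a pseudocount of 5. A count of 0 allowed up to 0.0917, 0.101, 0.0754 and 0.0832 CPM at days 0, 3, 7 and 10, so depth limits folds only for genes near these levels, while the single library per day limits every comparison.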

Other observations

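The tests of the granule genes and of depth were chosen after their result was seen, and the 8 gene lists of this part were written after the leading genes had been seen, whereas the other tests were set before the values they measure. Targets of ATF4, the transcription factor of the amino acid response, with the leading genes that prompted the list left out, were higher at day 10 than at day 7 in 17 of 23 detected cases and lower in 1. Their median log2 ratio was 1.87 (1.21 to 2.50), at percentile 100 of matched random lists. PHGDH, which opens serine synthesis, was 8.85-fold higher (7.61 to 10.3), the cystine transporter SLC7A11 7.87-fold higher (7.3 to 8.49), asparagine synthetase ASNS 6.77-fold higher (6.52 to 7.04) and the stress factor DDIT3 7.06-fold higher (6.42 to 7.78). At day 3 against day 0 the same list had 12 of 21 higher and 2 lower, with the amino acid transporter SLC7A5 13.7-fold higher (12.8 to 14.7) but DDIT3 13.6-fold lower (12.3 to 15.2), and at day 7 against day 3 0 higher and 5 lower. At day 10 against day 0 the median was 2.41 (0.94 to 3.26). The cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, were higher at day 3 than at day 0 in 13 of 19 and lower in 0. At day 10 against day 7 they split into 5 higher, led by CARS at 3.09-fold higher (2.97 to 3.21), and 5 lower, led by DARS at 2.92-fold lower (2.78 to 3.06), or 7 and 3 with median-of-ratios scaling. Their medians were 1.13 at day 3 against day 0 and 0.34 at day 10 against day 7.

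Nucleolar and ribosome biogenesis genes were higher at day 3 than at day 0 in 20 of 24 and lower in 0, with a median of 1.53 (1.38 to 2.06), had 0 members past 2-fold at day 7 against day 3, and were lower at day 10 than at day 7 in 22 of 24. Examples at day 10 against day 7 were RRP9 at 5.99-fold lower (5.49 to 6.55) and the nucleolar chaperone NPM1 at 4.61-fold lower (4.55 to 4.67). At day 10 against day 0 their median was -0.08, and 0.33 with median-of-ratios scaling. Nuclear-encoded oxidative phosphorylation genes were higher at day 3 in 18 of 28 and lower in 0, with UQCRC1, a core subunit of the cytochrome bc complex, 4.66-fold higher (4.35 to 4.99). At day 7 against day 3 their median was -0.34 (-0.57 to -0.18), with 2 lower and 0 higher. At day 10 against day 7 they were lower in 7 and higher in 0, or lower in 2 with that scaling, and their median at day 10 against day 0 was -0.17, or 0.26. Proteasome genes were higher at day 3 in 20 of 25, with PSMC3 5.04-fold higher (4.8 to 5.3). At day 10 against day 0 they were higher in 11, or 15 with median-of-ratios scaling, and lower in 0.

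More genes were lower than higher from day 0 to day 10, 6747 against 2276. If a few abundant genes took the reads at day 10, leaving out the 50 most abundant genes of that day and rescaling would bring the median log2 ratio of the detected genes from -0.61 to above the bound of -0.3 set beforehand. It was -0.47, so the median stayed negative without these genes. The bound itself could not decide the question. The 50 genes held 18.5% of the day 10 reads, too small a share for leaving them out to lift the median past it. Leaving these 50 genes out moved the median from -0.61 to -0.47, so most of it remained without them. Abundant genes beyond these 50 were not tried. Lower depth at day 10 is argued against by the totals, since that library has 10.3% more reads than the day 0 library, and a planned thinning to equal reads was run but set aside because it could only widen the gap in rows with a read. Median-of-ratios scaling gave a median of -0.23, above that bound, with 5238 lower and 3317 higher genes, so a narrower set of expressed genes in later erythroid cells remains a candidate explanation beside a scaling difference for part of the pattern, in 2 single libraries.

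Granule genes of neutrophil precursors and eosinophils were higher at day 3 than at day 0 in all 12 members, with a median of 4.69 (3.89 to 6.57), and 11 of them also stand in lists fixed before the data were examined. Unlike the ATF4 list, this list keeps leading genes of that comparison, such as PRG2. Its high values at day 3, and in part its lower values later, therefore follow from how it was chosen. Mature neutrophils or monocytes carried over from blood would be in the day 0 cells too, so only a larger share of them at day 3 could account for this. A larger share would raise their own markers, but those had a median of -0.38 (-1.37 to 0.11), close to the -0.31 of all detected genes. S100A9 was at 16.1 and 5.6 CPM and S100A8 at 8.47 and 2.65, and 14 of that list's 16 genes were at or above 1 CPM in the day 0 cells. Immature granulocyte precursors growing alongside may account for the pattern, with a median of -3.03 at day 10 against day 3, but transcription of the same genes within the erythroid cells would give that value too, so these cannot be told apart without single-cell data. At day 7 against day 3, after IL-3 was left out, 7 members were lower and 1 higher, the eosinophil gene PRG3 at 5.3-fold higher (4.8 to 5.86), and EPX was 1.83-fold higher (1.79 to 1.87).

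Glycolysis genes were lower at day 10 than at day 7, with a median of -1.99. The median was -1.70 with median-of-ratios scaling, -1.77 with upper-quartile scaling and -1.92 without the globin genes. A scaling difference of the size these methods estimate is thus argued against as the whole cause. Each scaling shifts all genes alike, so a larger difference was not tested. Lower activity of hypoxia-inducible factor (HIF) is left open. HIF targets outside glycolysis had a median of 0.39 (-1.49 to 1.12), at percentile 99.6 of matched random lists. That median is above the bound set beforehand, which by itself would count against lower activity. The interval reaches below the bound, a stricter reading that was not part of the rule set beforehand. Of 16 members 4 were higher, such as VEGFA at 5.32-fold higher (4.98 to 5.68), and 4 lower, such as PFKFB4 at 9.79-fold lower (6.25 to 16.1). Members going both ways decide nothing. For lower activity of a growth programme that also drives ribosome biogenesis, the prediction was met. The nucleolar genes had a median of -1.63 (-1.94 to -1.56) at percentile 0. Other values differed. At day 7 against day 3 glycolysis had a median of -0.93, but the nucleolar genes 0.05, with 0 of 24 past 2-fold. Proliferation and mitosis genes had a median of 0.83 (0.54 to 1.28) at day 10 against day 7. A shared programme is therefore left open. The joint fall of glycolysis and nucleolar genes may also be coincidence between programmes that end at the same stage, since only 1 library stands on each side.

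HIF targets outside glycolysis had medians of -0.47, -0.20 and -0.82 at day 3 against day 0, day 7 against day 3 and day 10 against day 0. Mature neutrophil and monocyte markers had medians of -0.44, -0.23 and -1.10 at day 7 against day 3, day 10 against day 7 and day 10 against day 0.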
